A study of Homo sapiens with 140 samples.

How the data were processed

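The data were 140 single-cell RNA libraries of the human cell line HEK 293T, made on a Fluidigm C1 microfluidic chip. Per the labels' protocols, cDNA was made in each capture chamber with the SMART-Seq v4 kit, a full-length poly(A)-primed method, and made into libraries with Nextera XT, which does not mark the strand. The libraries of one chip were pooled and sequenced on a NextSeq500 with reads of 16 and 59 bases, per the labels' protocols. No molecular identifiers are mentioned in the labels, so a count is a read and may hold PCR copies of one molecule.

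The authors deposited raw read counts per gene and cell in one table. FastQC, STAR and HTSeq, and the genome build GRCh38, are named in the submitters' processing notes. Their versions, their settings and the annotation release are not given in the sources used here. The deposited counts covered 58301 gene identifiers, of which 32012 had at least 1 count, and 5 summary rows that name no gene. Of these summary rows, 3 held only zeros, and the other rows counted reads in no annotated gene and reads that fitted more than 1 gene. Reads in no annotated gene made up a median of 8.39% of counted reads per library, with a range of 1.18% to 87.8%, and ambiguous reads a median of 7.68%. Both were left out of library totals. Genes were named and placed with GENCODE release 29 on GRCh38, in which 58038 identifiers were found, while 263 had no match in the reference tables. Near-identical genes and pseudogenes, overlapping genes and genes on opposite strands can share or lose reads in such counts, so values of ribosomal protein genes, histones and antisense genes are uncertain to that extent.

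Groups were taken from the part of each library's title that names the line and a number, which gave set HEK_147 with 35 libraries, set HEK_148 with 88 and set HEK_150 with 17. The labels do not say what these numbers stand for. The design text describes suspensions of about 10, 20 and 40 cells per µL loaded on chips with 96 traps, but no label ties a set to a suspension, so no set was assigned one. Libraries are numbered within each set in accession order, as names only. No separate cultures are named, so each set counts as 1 sample and its cells are not replicates. For that reason no test, p-value or standard error was computed between sets, and values stand side by side. Correlations across cells are descriptions of the cells of one set. No pair of libraries held identical counts.

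Cells needed at least 50000 counts on genes and 1000 detected genes, which all 140 passed. Doublets were not called, and no label says whether chambers with more than 1 cell were left out. For genes detected and cell cycle scores each cell was thinned without replacement to 500000 counts, the largest of the fixed depths that at least 90% of the cells of every set reached. This left out 1 cell of each set. For comparisons between sets, counts were summed over the cells of a set, divided by the set's total and scaled to CPM, and compared as log2(CPM + 1). Exact Poisson intervals of the sums and exact binomial (Clopper-Pearson) intervals of shares are at the 95% level and cover counting error only. Similarity was computed over genes with at least 10 CPM in 1 or more sets. Genes are not replicates.

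A total of 22 gene lists with 515 symbols, of which 514 were found, were fixed before the data were examined, as were the groups, the filters, the rule for named genes and the alternatives except those named as chosen later. A list's difference is the median over members with at least 5 CPM in either set, and lists with fewer than 3 such members are described by their genes only. The results of 1 gene and 1 list median are not reported here. A list's percentile among 10000 random lists of the same size matched on mean expression describes these libraries and is not a test. Random lists do not allow for members that vary together across cells, which can make a percentile more extreme. Cell cycle scores are the mean log2(CPM + 1) of a list less that of expression-matched control genes, and a cell was called S or G2/M by the higher score if above 0, and otherwise G1. Variability was the squared coefficient of variation of CPM across cells, taken as the residual from its trend on mean CPM, over 7055 genes with at least 10 mean CPM in every set. Co-variation of a list is the mean pairwise correlation of its genes across the cells of one set.

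Genes are named by 4 rules. They are the 15 nuclear genes of highest mean CPM. For each pair of sets they are up to 10 genes per direction with the largest log2 difference, among genes with at least 20 CPM in the higher set, a count in at least 50% of its cells, Poisson intervals that do not overlap, and a difference of at least 1 both in the sums and in the mean of per-cell CPM. They are up to 25 genes among the 200 most variable of every set. They are up to 4 members of each gene list.

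Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9. The code was tested on simulated data: of 32012 genes simulated between sets HEK_150 and HEK_147, 50 raised 4-fold had a median log2 difference of 1.98, and 50 lowered 4-fold one of -2.02. Alternatives varied the thinning, the read minimum, the cell filter, the way cells were combined, TMM and median-of-ratios scaling, the expression filter, the pseudocount, the control genes of the scores and the number of variable genes. Where a value had no test, it counted as moved if it left the spread over cells, the binomial interval, or 1 half-width of the random lists' range. A Spearman correlation counted as moved beyond 0.05, a median absolute log2 difference beyond 0.1, a named gene beyond 1.5-fold and a count of genes beyond 1.5 times.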

Results

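Transcriptomes of 140 single HEK 293T cells were measured as read counts per gene. HEK 293T is a fast-growing line derived from human embryonic kidney cells. The series was set up to benchmark how many cells the chip recovers. The libraries formed set HEK_147 (35 libraries), set HEK_148 (88) and set HEK_150 (17), and summed to 78037479, 209798185 and 27674082 counts on genes. Each set is 1 sample without replicates, so differences between sets have no replicate check, and intervals cover counting error only.

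Cells of set HEK_150 had fewer reads and fewer detected genes than those of the other sets. The median library held 2255340 counts in set HEK_147, 2552890 in set HEK_148 and 1827320 in set HEK_150, and single libraries ranged from 62876 to 3366854. At an equal depth of 500000 counts the median number of detected genes was 8247 in set HEK_147 (quartiles 7246 and 8932.5, 34 cells), 8240 in set HEK_148 (7808 and 8767.5, 87 cells) and 6525 in set HEK_150 (5902.5 and 7565, 16 cells). Without thinning the medians were 9631, 9676 and 7485 genes. The plot of genes against counts shows low-complexity libraries in each set. Set HEK_150 library 12 had 2207 genes from 1245846 counts.

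**Figure D1:**
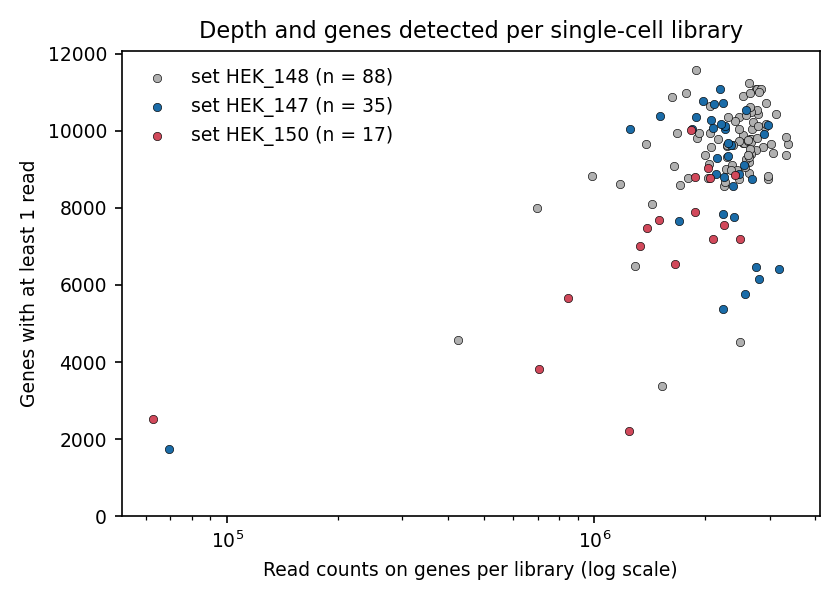
Genes with at least 1 read (vertical axis) against read counts on genes (horizontal axis, log scale), one point per library, coloured by set. The median library had 9631 genes in set HEK_147, 9676 in set HEK_148 and 7485 in set HEK_150.

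Transcripts encoded by the mitochondrial genome and ribosomal protein transcripts took a larger part of the counts in set HEK_150. The 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and ATP synthase, held a median of 3.35% of a library's counts in set HEK_147 (quartiles 2.95% and 3.93%), 2.75% in set HEK_148 (2.48% and 3.26%) and 4.71% in set HEK_150 (3.82% and 6.37%). Cytosolic ribosomal protein genes held 4.69%, 4.83% and 5.995%. MALAT1, a long noncoding RNA retained in nuclear speckles (chromosome 11, 65497688 to 65506516, plus strand, GRCh38), had a median of 1400, 1586 and 3441 CPM. Reads in no annotated gene, which include intronic reads, made up a median of 6.90%, 8.15% and 15.01% of counted reads. In 4 libraries mitochondrial mRNAs were nearly missing. Set HEK_147 library 4 held 2 such reads among 3181958, set HEK_147 library 6 held 3 among 2805657, set HEK_147 library 21 held 566 among 2756770, and set HEK_150 library 12 held 24 among 1245846. In the same libraries MALAT1 was at 1.26, 0.356, 2.54 and 1.61 CPM, while ribosomal protein genes held 4.604%, 5.29%, 3.59% and 10.7% of counts. At the other end, mitochondrial mRNA took 64.3% of counts in set HEK_150 library 9 and 62.2% in set HEK_148 library 88.

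**Figure D2:**
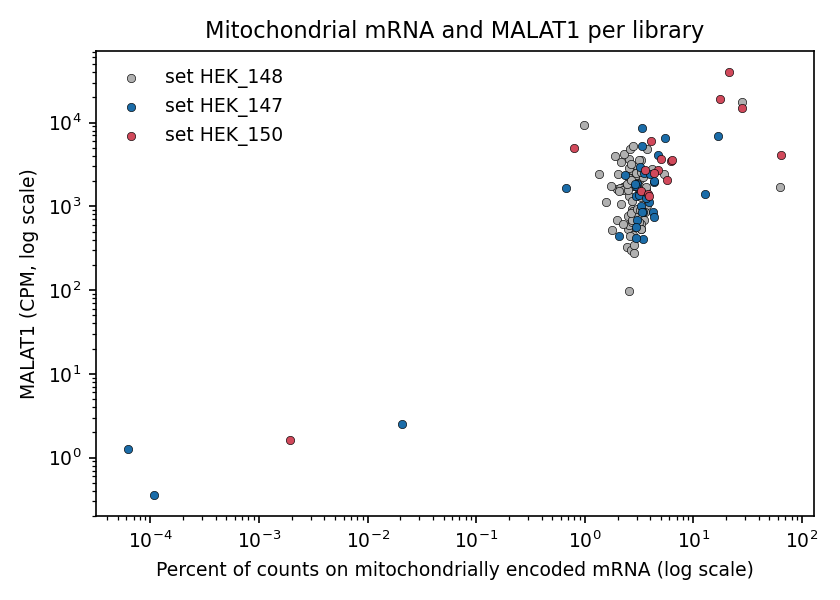
Percent of counts on mitochondrially encoded mRNA (horizontal axis, log scale) and MALAT1 in CPM (vertical axis, log scale), one point per library, coloured by set. The 4 libraries at the lower left have at most 0.0205% mitochondrial mRNA, and the lowest of the other 136 libraries has 0.669%.

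The nuclear genes of highest mean CPM included LDHB, LDHA, RACK1, the actin gene ACTG1 and the histone variant gene H2AZ1. LDHB, a lactate dehydrogenase subunit (chromosome 12, 21635342 to 21757857, minus strand), stood at 4184 CPM in set HEK_147 (Poisson interval 4170 to 4198), 4314 in set HEK_148 and 3597 in set HEK_150. LDHA, its partner subunit, stood at 4061, 3463 and 3229 CPM, and RACK1, a component of the small ribosomal subunit, at 3532, 3575 and 3781. Among markers of the HEK 293 lineage, STMN1, a microtubule regulator, was at 1488, 1316 and 1107 CPM, the intermediate filament gene VIM at 198, 142 and 191, the keratin KRT18 at 86.05, 77.5 and 89.8, and the neurofilament gene NEFL at 86.5, 70.1 and 27.6. Of the 18 genes on that list, 10 reached 5 CPM in set HEK_147, 10 in set HEK_148 and 12 in set HEK_150. KRT8, the usual partner of KRT18, was at 0.846, 1.46 and 6.90 CPM, and the kidney regulator PAX2 at 0.269, 0.419 and 0 CPM, where the exact Poisson interval of 0 counts reaches 0.133 CPM. In set HEK_150 the count of 12 includes NES, which had 5 reads in only 1 of 17 cells.

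Markers of other cell types were low. The blood and immune list held 7.2e-04% of the summed counts in set HEK_147, 7.0e-04% in set HEK_148 and 1.7e-04% in set HEK_150. The endothelial list held 3.6e-05% in set HEK_147 and the fibroblast list 8.3e-04%. The intestinal list held 0.00219%, 0.00272% and 0.00344%, with CDX2, an intestinal homeobox gene, at 14.5, 21.96 and 18.7 CPM. The differentiated kidney list held 0.00330%, 0.00317% and 0.00787%, with the endocytic receptor gene LRP2 at 16.5, 22.4 and 67.3 CPM. The keratinocyte list held 0.0278%, 0.0285% and 0.0323%, nearly all of it from DMKN at 175, 165 and 181 CPM and KRT10 at 102.5, 120 and 142 CPM, which were read in most cells of every set.

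Sets HEK_147 and HEK_148 were closer to each other than either was to set HEK_150. Across 9492 genes the Spearman correlation of CPM was 0.957 between sets HEK_148 and HEK_147, 0.858 between sets HEK_150 and HEK_147, and 0.871 between sets HEK_150 and HEK_148. The median absolute log2 difference was 0.25, 0.53 and 0.50, and 93.6%, 75.2% and 77.02% of the genes lay within 2-fold.

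Between sets HEK_148 and HEK_147, hypoxia and glycolysis genes were lower in the summed counts of set HEK_148, and less so in its median library. Of the 18 hypoxia and glycolysis genes, 17 were lower, with a median log2 difference of -0.65 (percentile 0.00 among random lists). BNIP3, a mitophagy receptor, differed by -0.82, PDK1, which restrains pyruvate oxidation, by -1.29, and LDHA by -0.23. Without set HEK_147 library 12 the median was -0.42, and the list's mean log2 CPM in the median library differed by -0.16. The G2/M list was lower by a median of -0.16 (41 of 54 genes lower, percentile 0.00), with -0.10 without set HEK_147 library 12 and -0.047 without the deepest 10% of cells. The 13 mitochondrial mRNAs had a median of -0.06 (percentile 2.86), which was 0.09 without set HEK_147 library 20. Proteasome genes were higher by 0.12 (26 of 31 genes, percentile 99.6). Replication-dependent histones, most of whose transcripts lack a poly(A) tail, had a median of -0.92 over 11 genes (percentile 0.02), which was -0.14 without set HEK_147 library 7.

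For the same pair of sets, 10 genes per direction were named for the size of their difference. DDIT4, an inhibitor of mTOR signalling induced by stress (chromosome 10, 72273920 to 72276036, plus strand), stood at 40.9 CPM in set HEK_147 (39.5 to 42.4) and 10.6 in set HEK_148 (10.2 to 11.05), a log2 difference of -1.85. ACSF3, a mitochondrial acyl-CoA synthetase, differed by -1.83 (-0.74 in the median cell), YPEL3 by -1.63, EIF4E3, a cap-binding protein, by -1.60 and CHMP7, an ESCRT protein of nuclear envelope sealing, by -1.46. CALCB, a calcitonin gene-related peptide, had the largest difference upward in set HEK_148 at 2.33, but the value was -0.07 without set HEK_148 library 8. ZBTB1 and BEND4 were higher by 1.89 and 1.79, and by 0.96 and 0.95 without set HEK_148 library 69. VPS16, of the endosomal tethering complexes, was higher by 1.86, RNF150 by 1.81 (2.41 without set HEK_147 library 17) and THADA by 1.64 (0.38 in the median cell). Of the 10 genes named in each direction, 7 that were higher in set HEK_148 and 7 that were higher in set HEK_147 still differed by at least 2-fold without their most influential library.

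Set HEK_150 had more mitochondrial, ribosomal protein and nuclear noncoding RNA than the other sets, and less of the G2/M, heat shock and p53 target genes. All 13 mitochondrial mRNAs were higher, with a median log2 difference of 0.84 from set HEK_147 and 0.87 from set HEK_148 (percentile 100 in both). Their mean pairwise correlation across cells was 0.94, 0.58 and 0.97 in sets HEK_147, HEK_148 and HEK_150, so they are not 13 separate observations. Without set HEK_150 library 16 the mitochondrial medians were 0.63 and 0.72. MT-CO1, a cytochrome c oxidase subunit, stood at 7900, 6328 and 13813 CPM in sets HEK_147, HEK_148 and HEK_150, and MT-ND4 at 5631, 5132 and 10863. Ribosomal protein genes were higher by a median of 0.44 and 0.38 (72 and 70 of 78 genes). Among 6 nuclear long noncoding RNAs 5 were higher, with medians of 0.77 and 0.91 (percentiles 99.95 and 99.98). MALAT1 was higher by 1.38 and 1.39. KCNQ1OT1, the imprinted antisense transcript of KCNQ1, was higher than in set HEK_147 by 3.05 (1.99 without set HEK_150 library 13), though reads of KCNQ1 and other overlapping genes cannot be parted from it without strand information. Without set HEK_150 library 10 the noncoding median against set HEK_147 was 0.38. Reads in no annotated gene were also a larger share in set HEK_150, as given above.

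The lists lower in set HEK_150 included G2/M, heat shock and p53 target genes, while the unfolded protein list was higher in the sums. G2/M genes had medians of -0.70 against set HEK_147 and -0.48 against set HEK_148 (43 and 44 of 54 genes lower, percentile 0.00 in both). BUB1, a spindle checkpoint kinase, differed by -2.43 and -1.87, and CDK1 by -0.59 and -0.43. Heat shock genes had medians of -0.69 and -0.71 (13 of 15 lower in both), with the co-chaperone DNAJB1 at -1.59 and -1.32 and HSPA8 at -0.48 and -0.75. The p53 targets had medians of -1.03 and -1.15 (10 of 13 lower, percentiles 0.28 and 0.03), with CDKN1A, a cell cycle inhibitor, at -1.03 and -0.89 and SESN1 at -2.44 and -1.48. The p53 list was low, at 0.0389%, 0.0344% and 0.0166% of the summed counts of sets HEK_147, HEK_148 and HEK_150. In these sets 13, 13 and 10 of its 16 genes reached 5 CPM. Proteasome genes had medians of -0.29 (percentile 3.81) and -0.41 (percentile 0.03). Hypoxia and glycolysis genes had a median of -0.49 against set HEK_147 (percentile 0.78), which was -0.22 without set HEK_147 library 1. Against set HEK_148 their median was 0.17 (percentile 85.9), and 0.29 without set HEK_150 library 14. The unfolded protein and integrated stress response list had medians of 0.48 and 0.71 (percentiles 99.97 and 100), led by the ER chaperone gene HSPA5 at 1.33 and 1.40, but without set HEK_150 library 3 the medians were -0.31 and -0.06.

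The remaining list differences lay inside the ranges of the random lists, except that of nuclear-encoded oxidative phosphorylation genes between sets HEK_150 and HEK_147. For sets HEK_148 minus HEK_147, HEK_150 minus HEK_147 and HEK_150 minus HEK_148, the S phase medians were -0.02, -0.08 and -0.13, the immediate early medians 0.13, -0.15 and -0.12, the cholesterol synthesis medians 0.11, 0.07 and -0.03, the interferon response medians -0.25, -0.51 and -0.27, and the HEK 293 lineage medians 0.06 and 0.43 for the pairs with set HEK_150. Without set HEK_147 library 21 the interferon response median of set HEK_150 minus set HEK_147 was -0.14, and over all alternatives it ranged from -1.60 to 0.32. That of set HEK_148 minus set HEK_147 was -0.39 without set HEK_148 library 26. That of set HEK_150 minus set HEK_148 was -0.47 without set HEK_150 library 6. Without set HEK_150 library 2 the HEK 293 lineage median against set HEK_148 was 0.14, and without set HEK_147 library 11 that against set HEK_147 was 0.32. The immediate early medians were 0.28 without set HEK_147 library 29, -0.33 without set HEK_150 library 11 and -0.31 without set HEK_150 library 2. Without 1 library the S phase median of set HEK_148 minus set HEK_147 was 0.05 (set HEK_147 library 21), and the cholesterol synthesis median of set HEK_150 minus set HEK_147 was -0.08 (set HEK_150 library 17) and that against set HEK_148 was -0.21 (set HEK_150 library 1). Nuclear-encoded oxidative phosphorylation genes had medians of 0.04, 0.07 (percentile 97.9) and -0.01, beside the mitochondrial mRNA medians of -0.06, 0.84 and 0.87. Ribosomal protein and heat shock genes had medians of 0.02 and 0.05 between sets HEK_148 and HEK_147, where the unfolded protein list stood at -0.01, the p53 targets at -0.08 and the nuclear noncoding RNAs at 0.08. For this pair the ribosomal protein median was 0.04 without set HEK_147 library 20, and the heat shock median 0.003 without set HEK_148 library 20. The unfolded protein median was -0.06 without set HEK_147 library 4. The p53 median was -0.17 without set HEK_148 library 48, and the noncoding median 0.23 without set HEK_147 library 11. Histones stood at -0.41 and 0.30 in set HEK_150 against sets HEK_147 and HEK_148, and at -0.74 and 0.11 without set HEK_150 libraries 1 and 17 respectively.

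**Figure D3:**
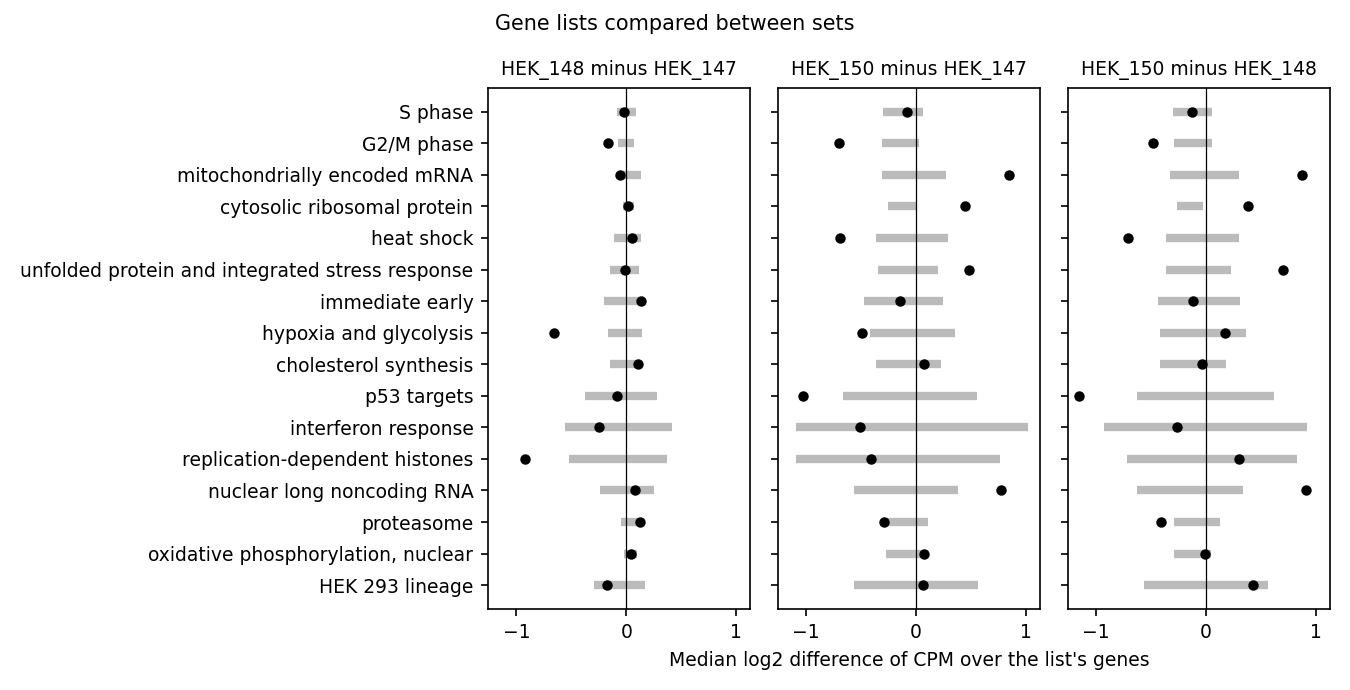
Median log2 difference of CPM over each gene list (black points, horizontal axis) for the 3 pairs of sets, for lists with at least 3 genes used. Grey bars span the middle 95% of 10000 random lists matched on expression. Mitochondrial mRNAs lie at 0.84 and 0.87 for set HEK_150 and at -0.06 between sets HEK_148 and HEK_147.

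Genes named as lower in set HEK_150 were nearly unread there. CHMP7 (chromosome 8, 23243637 to 23262000, plus strand) stood at 59.5 CPM in set HEK_147, 20.95 in set HEK_148 and 0.795 in set HEK_150 (0.498 to 1.20), OTUD4, a deubiquitinase, at 55.1, 43.5 and 0.795 CPM, and MAPK14, the stress kinase p38 alpha, at 50.1, 30.3 and 0.723. Against set HEK_147, CHMP7 differed by -5.07 (-5.92 without set HEK_150 library 15) and MAPK14 by -4.89 (-5.67 without set HEK_150 library 17). FRS2, an adaptor of growth factor receptors, differed by -4.75 and -4.26, and ALG1, a mannosyltransferase of N-glycan assembly, by -4.25 and -4.19. All 10 such genes against each other set kept at least a 2-fold difference without their most influential library. For genes nearly unread in set HEK_150, leaving out 1 library could hardly undo the difference, so this says little. In the median cell 9 of 10 genes kept it against set HEK_147 and 8 of 10 against set HEK_148, where CHMP7 differed by only -0.24. B3GNT2 differed by -0.55 and -0.56 in the median cell. The genes were picked for the largest differences. Cells of set HEK_150 also had fewer genes at equal depth, with a median of 6525 against 8247 and 8240. How far lower detection accounts for the near absence of these genes was not tested.

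Most genes named as higher in set HEK_150 owed their value to 1 library. INO80E differed by 4.22 from set HEK_147 and 4.03 from set HEK_148, and by 0.35 and 0.16 without set HEK_150 library 9. AP2A2 (3.43 and 3.25), NISCH (2.99 and 2.90), ADNP2 (2.83 and 3.42) and RPL39L (2.75 and 2.64) changed sign against both sets without set HEK_150 library 12, the library with 2207 genes and nearly no mitochondrial mRNA, as did ZIC2 against set HEK_147. NIN, EARS2 and FLII were higher than in set HEK_148 by 3.07, 2.92 and 2.56, and by 0.66, 0.41 and 0.40 without that library. KCNQ1OT1 (1.99 without set HEK_150 library 13), TRIM11 (1.90 without library 6), MYLIP (2.50 without library 10) and CCDC80 (2.49 without library 6) remained higher than in set HEK_147. Against set HEK_147, 4 of the 10 genes kept at least a 2-fold difference without their most influential library, and against set HEK_148, 2 of 10.

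By their scores most cells of each set were called S phase or G2/M. After thinning, 17 of 34 cells of set HEK_147 were called S phase (50%, exact binomial interval 32.4% to 67.6%), 40 of 87 of set HEK_148 (45.98%, 35.2% to 57.002%) and 10 of 16 of set HEK_150 (62.5%, 35.4% to 84.8%). G2/M calls were 16 (47.1%), 42 (48.3%) and 6 (37.5%), and G1 calls 1, 5 and 0, where 0 of 16 allows up to 20.6%. Without thinning, S phase calls were 51.4%, 48.9% and 58.8%. The intervals cover the counting of cells within a set, and no test was made between sets. The scores are relative to control genes, and 3, 7 and 0 cells lay within 0.1 of a boundary. S and G2/M scores were opposed across cells, with Pearson r = -0.71 and Spearman rho = -0.79 in set HEK_147, -0.67 and -0.69 in set HEK_148, and -0.85 and -0.86 in set HEK_150. Leaving out the 2 cells farthest from the median S score gave r = -0.73, -0.67 and -0.85. A G1 call needs both scores at or below 0, which opposed scores rarely give. The few G1 calls therefore do not measure the share of cells in G1. S phase genes varied together more than random lists in sets HEK_147 and HEK_148 (mean pairwise correlation 0.20 and 0.27, percentiles 99.99 and 99.94), as did G2/M genes (0.25 and 0.29, percentile 100 in both). In set HEK_150 the percentiles were 95.7 and 30.4. Co-variation was not recomputed without the libraries that nearly lacked mitochondrial mRNA.

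**Figure D4:**
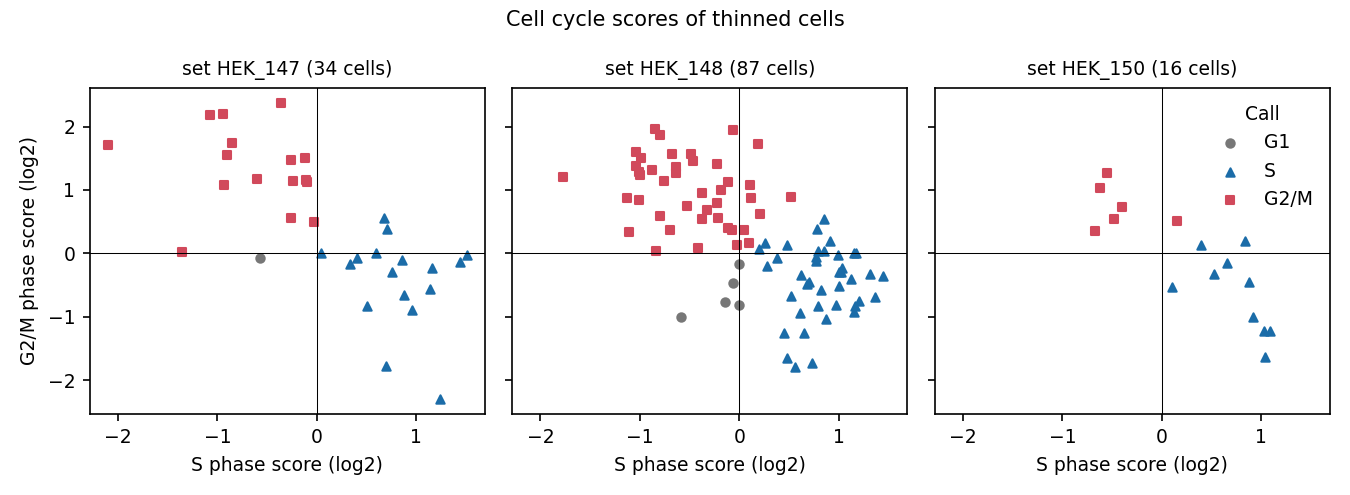
S phase score (horizontal axis, log2) and G2/M score (vertical axis, log2) of each thinned cell, one panel per set, with marker shape and colour giving the call. Pearson r is -0.71 in set HEK_147, -0.67 in set HEK_148 and -0.85 in set HEK_150.

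A small group of genes varied strongly between cells in every set. Of the 200 most variable genes of each set, 12 were shared by all, where independent lists would share 0.161, and 40 were shared by sets HEK_147 and HEK_148, 19 by sets HEK_147 and HEK_150 and 17 by sets HEK_148 and HEK_150, against 5.67 expected for each pair. The 12 genes were the mitochondrial genes MT-CO2, MT-ATP6, MT-CYB, MT-ND1, MT-CO3 and MT-RNR1, MALAT1, the glucocorticoid-induced gene TSC22D3, the carbonic anhydrase gene CA2, the mitotic ubiquitin-conjugating enzyme gene UBE2C, the scaffold protein gene AKAP9 and IDI1 of isoprenoid synthesis. CA2 and UBE2C were not among the shared genes with the stricter cell filter or without the 4 libraries with almost no mitochondrial mRNA. AKAP9 was not among them with the stricter cell filter, and MT-RNR1 was not with at least 50 mean CPM. With thinned cells MT-ATP6, MT-CYB, MT-ND1, MT-CO3 and AKAP9 were not shared, and MT-CO2 and MT-RNR1 were. Thinning left out 1 cell of each set, which in set HEK_148 was library 88, with 62.2% mitochondrial mRNA. CA2 (chromosome 8, 85463852 to 85481493, plus strand) ranged from 0 to 6392 CPM between cells of set HEK_147 with a median of 681, from 0 to 4693 in set HEK_148 with a median of 958, and from 0 to 6270 in set HEK_150 with a median of 630. TSC22D3 ranged from 0 to 3465, 3156 and 3513 CPM around medians of 357, 210 and 36.9. Ribosomal protein genes were among the least variable for their level, with a median percentile of 7.20, 6.80 and 10.8 among 7055 genes, while G2/M genes had median percentiles of 81.1, 88.8 and 65.7.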

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

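No test was run on the values in this part. Reads that fell in no annotated gene are outside the gene counts, and in each set 1 library held the most of them. They made up 87.8% of the counted reads of set HEK_147 library 22, 25.9% of set HEK_148 library 88 and 48.4% of set HEK_150 library 9, against medians of 6.90%, 8.15% and 15.01% in those sets. No control library is among those analysed here, and the cause was not tested.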

How the results depend on the processing

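The alternatives without 4 libraries, without set HEK_150 library 12 and without the most influential library, and the stricter cell filter for named genes, were chosen after seeing the data. No paired analysis was possible because each set is 1 sample and library numbers in accession order pair nothing. Of the other results, all phase shares stayed within their intervals under every alternative run. Those intervals were wide, such as 35.4% to 84.8% for S phase in set HEK_150. The alternatives rescored nearly the same cells, so this says little about the phase shares. The mitochondrial and ribosomal protein shares stayed within 1 standard deviation over cells. For mitochondrial mRNA that was 15.8 around a median of 4.71% in set HEK_150 and 6.88 around 2.75% in set HEK_148. For ribosomal protein genes it was 2.41 around 5.995% in set HEK_150. Limits this wide could hardly be left, so the check says little about these shares. The median of all genes was -0.02, -0.11 and -0.09 for the 3 pairs of sets, and with TMM 0.04, -0.08 and -0.12. For set HEK_150 minus set HEK_147 the ranges over all alternatives were -0.84 to -0.62 for the G2/M list, 0.39 to 0.49 for ribosomal protein genes, -0.74 to -0.45 for heat shock genes and -1.36 to -0.80 for p53 targets. The ranges were wider for mitochondrial mRNA, at 0.63 to 1.34, and reached from 0.27 to 0.80 for nuclear noncoding RNA. A minimum of 5 reads gave a median of 6526.5 genes in set HEK_147 and 6535 in set HEK_148, and no thinning 9676 in set HEK_148. The mean of per-cell CPM gave mitochondrial list differences of 1.34 and 1.35 for set HEK_150 minus sets HEK_147 and HEK_148, and -0.053 for nuclear oxidative phosphorylation genes against set HEK_147. The median absolute log2 difference of set HEK_150 minus set HEK_147 was 0.64 over genes with at least 1 CPM and 0.41 with at least 50, and of set HEK_150 minus set HEK_148 it was 0.40 with at least 50. Without the deepest 10% of cells the G2/M difference of set HEK_148 minus set HEK_147 was -0.047, and the unfolded protein list of set HEK_150 was at -0.40 against set HEK_147 and -0.26 against set HEK_148. Without its most influential library that list was at -0.31 and -0.062, the hypoxia list of set HEK_148 minus set HEK_147 at -0.42 and the G2/M list of set HEK_150 minus set HEK_148 at -0.67. Genes variable in every set numbered 38 with the top 500, 22 with 50 mean CPM, 23 with the stricter cell filter and 19 without 4 libraries; 12, 11, 9 and 10 of them were among the 12. With thinned cells they numbered 9, of which 7 were among the 12. In the median cell 32 differences of named genes moved, 12 changed sign and 16 stayed. CALCB was at -3.02 in the median cell and -0.068 without set HEK_148 library 8. Set HEK_150 minus set HEK_147 gave, in the median cell, -0.21 for AP2A2, -1.73 for ZIC2, -1.91 for ADNP2 and -0.23 for RPL39L. With the stricter filter it gave -0.43 for AP2A2, -0.25 for NISCH, -0.10 for ZIC2, -0.80 for ADNP2 and -0.052 for RPL39L, and without set HEK_150 library 12 -0.44, -0.25, -0.11, -0.80 and -0.054. Set HEK_150 minus set HEK_148 gave, in the median cell, -0.050 for INO80E, -1.003 for ADNP2, -1.14 for AP2A2, -0.88 for NIN, -0.25 for NISCH, -0.46 for RPL39L and -2.48 for FLII. With the stricter filter it gave -0.22 for ADNP2, -0.62 for AP2A2, -0.34 for NISCH and -0.16 for RPL39L, and without set HEK_150 library 12 -0.22, -0.62, -0.34 and -0.16. The cause was not tested except where a library is named. Depth limits low genes, since the exact interval of 0 counts in set HEK_150 reaches 0.133 CPM.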

Other observations

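The tests on libraries with almost no mitochondrial mRNA, and those of set HEK_150 on a few libraries and on genes detected, were chosen after the results were seen. Several stress and metabolic gene lists varied together from cell to cell in set HEK_147. Immediate early genes had a mean pairwise correlation of 0.25 (percentile 100 among random lists), heat shock genes 0.26 (99.96), cholesterol synthesis genes 0.19 (99.95) and hypoxia and glycolysis genes 0.18 (99.98). In set HEK_148 the same lists had 0.16 (100), 0.24 (83.3), 0.16 (83.8) and 0.09 (95.5). In set HEK_150 they lay at percentiles 72.9, 70.9, 31.6 and 32.4. The unfolded protein and integrated stress response list lay at percentiles 98.8, 98.9 and 98.1 in sets HEK_147, HEK_148 and HEK_150. The p53 targets varied together in set HEK_148 (0.09, percentile 99.97) and not beyond random lists in set HEK_147 (0.02, percentile 12.4). The cells of set HEK_147 include libraries with almost no mitochondrial mRNA, and co-variation was not recomputed without them. Whether these libraries carry the co-variation of the lists in that set was not tested. The nuclear noncoding list had 0.41 (percentile 100) in set HEK_147, against 0.05 (percentile 22.15) in set HEK_148.

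Mitochondrial mRNA and MALAT1 were both nearly missing from set HEK_147 libraries 4, 6 and 21 and set HEK_150 library 12. A cell of another type is argued against, since no other-type marker list exceeded 0.0341% of counts, while few captured molecules stay open, since at least 72.9% of 85 abundant nuclear genes had 5 reads in each library but genes at equal depth numbered only 5094, 4872, 5316 and 1641. A candidate explanation for the libraries of set HEK_147, found and tested on the same data, is that mainly RNA of the soluble cytosol was taken up, but set HEK_150 library 12 held 3448 CPM of the mitochondrial rRNA MT-RNR2, against 0.314, 0.356 and 60.9 in the others. A list of mRNAs translated at the ER membrane, written after genes missing from set HEK_150 library 12 had been seen and so judged on set HEK_147, held 0.199%, 0.233% and 0.318% of counts in libraries 4, 6 and 21 (highest percentile among all libraries 2.88), against a median of 1.60%, while mRNAs of soluble proteins were at percentiles 91.4, 98.6 and 100. Reads in no annotated gene were also low there, at 1.34%, 1.41% and 1.18%, and whether lysis was incomplete or a cell fragment was caught stays open.

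Set HEK_150 differed from both other sets in mitochondrial mRNA and in its profile across genes. A few libraries as the whole cause of its mitochondrial mRNA are argued against, since the log2 ratio of median percents was 0.78 to set HEK_148 and 0.49 to set HEK_147, although the latter is well below the 0.84 of the sums. Fewer libraries in the sum is argued against too, since the lowest Spearman correlation with set HEK_147 over 100 draws of 17 libraries of set HEK_148 was 0.913, above the 0.858 of set HEK_150. Fewer detected genes stay open, since Spearman rho with mitochondrial mRNA was 0.37, 0.109 and -0.20 in sets HEK_147, HEK_148 and HEK_150, and Pearson r, at 0.19, -0.51 and -0.26, was 0.14, -0.05 and -0.50 without the 2 extreme cells of each. The labels name no chip or sequencing run for a library, so a batch difference stays open too, and no biological explanation was tested.

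The hypoxia and glycolysis list was lower in set HEK_148 than in set HEK_147. Scaling of the totals is argued against, since the smallest difference with TMM or median-of-ratios factors was -0.60. The median library differed by only -0.16 in the list's mean log2 CPM, a measure unlike the median over genes in the sums. Its standard deviation over libraries was 1.30 in set HEK_147 and 0.78 in set HEK_148. Set HEK_147 reached further at both ends, from 0 to 7.67, against 1.35 to 6.41 in set HEK_148. The lower quartiles were 4.24 and 4.29 and the upper quartiles 5.44 and 5.00. Cells in the upper part of set HEK_147 may thus carry the difference in the sums. No biological explanation was tested.

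Libraries were not spread evenly over the plate positions in their titles, and the grouping of columns was chosen after the positions were seen. Of the 52 libraries of sets HEK_147 and HEK_150, 51 lay in columns 1 to 3 and 7 to 9. Set HEK_148 lacked 1 of 48 wells in those columns and 7 of 48 in columns 4 to 6 and 10 to 12. Of the 17 wells of set HEK_150, 15 also held a library of set HEK_147. The numbers after the letter S in the titles ran from 23 to 57 in set HEK_147 and from 58 to 74 in set HEK_150, and each of these numbers also occurred in set HEK_148.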
